A study of Homo sapiens with 120 samples.

How the data were processed

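RNA was sequenced from 120 wells of U2OS cells, a human osteosarcoma line, that the labels place in 40 groups of 3. Per the labels' protocols, cells were grown and treated in 24-well plates in triplicate, libraries were made with a directional kit that marks the strand (NEBNext Ultra II Directional), and they were sequenced on a NovaSeq instrument. Whether the counting used the strand is not given in the sources used here, so a gene and an antisense partner are not separated with certainty. The submitters' processing notes name FastQC 0.11.5, Salmon 0.9.1 and the build GRCh38, but not how each was set. The authors deposited a table of estimated counts per gene, which the values show to be expected counts, since only 49.5% of the non-zero entries are whole within 1e-05. They also deposited a table of TPM, which scales each library's transcript abundances to 1 total. In the deposited TPM table every entry with an estimated count of 0 holds 0.063122, a floor shared with 194117 entries whose count is above 0, and the columns sum to 1001150 to 1001825. Each of the columns in both tables matched the label of 1 sample, and 0 columns were left unmapped.

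The tables hold 57665 genes with Ensembl identifiers and symbols, of which 1911 genes share their symbol with another gene. For 53330 identifiers the same identifier and version was found in GENCODE 29, from which chromosome, start and end on GRCh38 were taken, and for the others, DDIT3, FKBP1A and SPX among them, no position is given. Totals of the estimated counts ran from 1.29e+07 to 5.65e+07 per library with a median of 2.23e+07. Genes of the mitochondrial genome took 2.72% to 6.61% of a library and its 10 highest genes took 5.39% to 15.89%. No replicates matched within sampling noise, so each library counted as 1. Intervals and floors cover counting error only.

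Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter by group with a minimum count of 10, which left 26998 genes, and libraries were scaled by TMM (factors 0.839 to 1.169). One quasi-likelihood fit held all 120 libraries and 40 groups, with a negative binomial dispersion of 0.00142, 12.7 prior and 80 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The ± beside a log2 fold change is an approximate standard error from that fit. Beside CPM (counts scaled to library size) it is the SD between libraries, which over several times includes change with time.

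Each treatment was compared with untreated wells of the same line and time, averaged over 4, 8, 16 and 24 h, and also at each time. No untreated wells were collected at 2 h, and that time was set against untreated wells at 0 h. The difference between the lines in a treatment's effect was tested as an interaction, the change of an effect between 4 and 24 h by an F-test on 3 degrees of freedom, and treatments directly against each other over 5 times. Comparisons against the same untreated wells share their chance values. For their overlap, 10 simulations of unchanged treatments, the overlap of independent lists, and untreated libraries parted into groups of 6 stand beside the observed values.

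The comparisons, tests, gene lists and naming rule, and all alternatives but a pair named as added later, were fixed before the data were examined. The 28 lists were ATF4/CHOP targets, serine and one-carbon enzymes, cytosolic aminoacyl-tRNA synthetases, amino acid transporters, ER chaperones, ER-associated degradation and secretory genes of the XBP1 type, NRF2 antioxidant genes, HSF1 heat shock genes, metallothioneins and zinc export, immediate early genes, cholesterol synthesis, mitosis, DNA replication, p53 targets, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrially encoded proteins, NF-kB and inflammatory genes, interferon-stimulated genes, extracellular matrix, autophagy, hypoxia and glycolysis, the eIF2 pathway, genes that may share sequence with the construct, epithelial markers, blood cell markers, osteoblast markers and housekeeping genes. None was chosen on these samples. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 364 tests of the 28 lists in 13 comparisons, and again with a correlation estimated per list. Of the 198 calls with the preset correlation, 73 held with the estimated one.

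Named genes were, for each treatment of Dmr-PERK cells, the 6 highest and 6 lowest called log2 fold changes at a mean of at least 5 CPM in the higher group and the same sign at all 4 times, then the 3 members of each list with the smallest adjusted p (its most abundant member where none passed), and a fixed panel (ATF4, DDIT3, ASNS, TRIB3, CHAC1, SESN2, PPP1R15A, HSPA5, HERPUD1, DNAJB9, HMOX1, GCLM and HSPA1A). For the other comparisons they were the 5 highest and 5 lowest, without the rule on sign, and the panel. A fold against a group at a count of 0 is given as a lower bound from 3 counts over that group. Genes with near-identical copies, such as HSPA1A and HSPA1B, HSPA6 and HSPA7, the metallothioneins and the CLUHP, GAGE12 and DUX4 families, are uncertain because estimated counts can be divided among copies. Some genes that the rule names are not reported here.

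The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, library totals without a composition factor, no filter on low counts, a stricter filter (1 CPM in 60 libraries), limma-trend on log2 TPM with pseudocounts of 1 and 0.1, a fit of each comparison's own libraries, all untreated times averaged as the control, the replicate number as a block, a minimum of 2-fold, fry for the lists, and leaving out each replicate or library. Added after seeing the data were a mean over 8, 16 and 24 h and a fit without a pair of libraries that stood apart (Parental arsenite 24 h replicate 3 and Dmr-PERK arsenite 4 h replicate 3). On data simulated from the libraries of the Dmr-PERK dimerizer comparison (26699 genes), edgeR recovered 57.8% of 83 genes changed 1.5-fold, 76.4% of 55 changed 2-fold and 85.2% of 61 changed 4-fold, with 4 false calls among 26500 unchanged genes. There camera (either correlation) and fry called the 1 changed list and 0 of 27 random lists. So few changed genes cannot test false list calls.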

Results

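Gene expression was measured by RNA sequencing in U2OS cells, in a parental form and in a derivative that carries Dmr-PERK. PERK, encoded by EIF2AK3, is a kinase of the endoplasmic reticulum (ER) that phosphorylates the translation factor eIF2α. Per the series text, Dmr-PERK joins the kinase domain of mouse PERK to DmrB, an FKBP-derived domain that the ligand AP20187 brings together in pairs. The cells were left untreated or given 0.2 nM AP20187 (the dimerizer), 100 nM thapsigargin, which blocks the calcium pump of the ER and causes ER stress, or 0.05 mM arsenite, an oxidant that also damages proteins. The doses were chosen, per the series text, to bring eIF2α phosphorylation to similar levels. Treated wells were collected at 2, 4, 8, 16 and 24 h and untreated wells at 0, 4, 8, 16 and 24 h, in triplicate.

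Library totals in Dmr-PERK cells ran from 1.82e+07 to 2.77e+07 untreated, 1.68e+07 to 3.27e+07 with dimerizer, 1.53e+07 to 5.65e+07 with thapsigargin and 1.29e+07 to 5.61e+07 with arsenite. In Parental cells they ran from 1.68e+07 to 4.61e+07 untreated, 1.69e+07 to 5.41e+07 with dimerizer, 1.80e+07 to 4.21e+07 with thapsigargin and 1.73e+07 to 2.90e+07 with arsenite. Replicates of a group had Pearson correlations of log2(CPM + 1) of 0.986 to 0.999 across all 57665 genes, which are not independent replicates. Nothing in the labels says that the 3 wells of a group came from separate cultures, so the p-values measure the spread between these wells, which may be technical.

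Untreated cells of both lines were compared to see what the construct line differs in before any treatment. Counts assigned to EIF2AK3 (ENSG00000172071.11, chromosome 2, 88556741 to 88627576 on GRCh38) were 930.2 ± 80.4 CPM in Dmr-PERK cells and 33.9 ± 10.1 in Parental cells (SD, n = 15 each), a log2 difference of 4.83 ± 0.02. Counts assigned to FKBP1A (ENSG00000088832.15), the FK506-binding protein from which DmrB derives, were 1217 ± 102 and 260.5 ± 19.6 CPM, a log2 difference of 2.22 ± 0.02. Both genes share sequence with the construct, and estimated counts do not separate its RNA from that of the genes. The edgeR adjusted p was 3.66e-120 for EIF2AK3 and 6.35e-104 for FKBP1A.

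**Figure D1:**
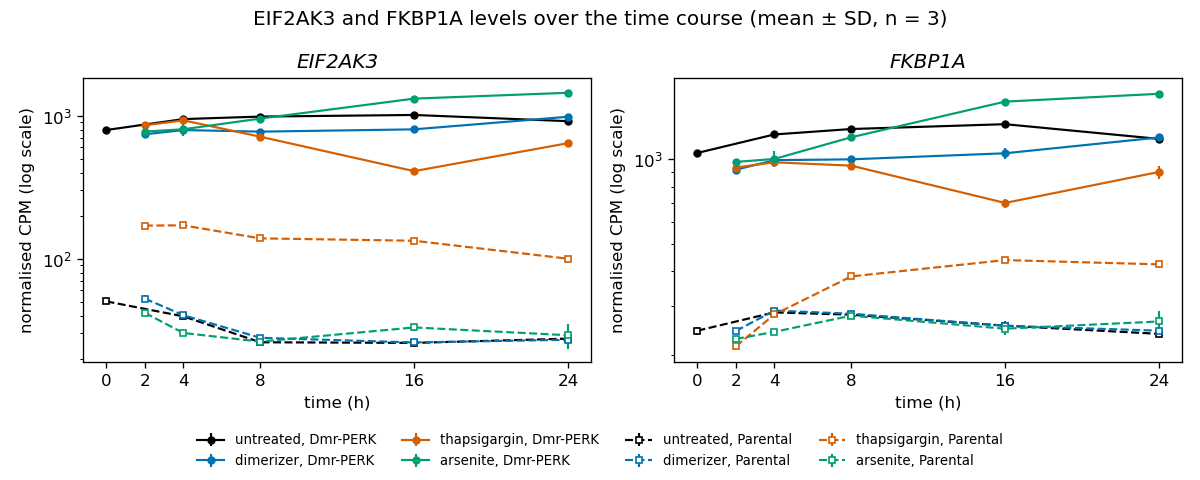
CPM (log axis) assigned to EIF2AK3 and FKBP1A in every group, plotted against hours (mean ± SD of 3 libraries). EIF2AK3 averaged 930.2 CPM in untreated Dmr-PERK cells and 33.9 in untreated Parental cells, and FKBP1A averaged 1217 and 260.5.

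The lines also differed widely beyond the construct. PASD1 (8.32 ± 0.12), GAGE12C (6.60 ± 0.18), GAGE12H (5.48 ± 0.12) and IL13RA2 (5.63 ± 0.13), antigens of testis and tumors, were higher in untreated Dmr-PERK cells on the log2 scale. CNGB1 (-7.79 ± 0.06), WNT6 (-7.36 ± 0.13), ART5 (-7.32 ± 0.16) and DPYSL5 (-7.17 ± 0.09) were lower. CHRNA4, a nicotinic receptor subunit, had a count of 0 in all 15 untreated Dmr-PERK libraries against 13.7 ± 1.79 CPM in Parental cells, at least 1550-fold lower. ATF4 (0.03 ± 0.02, edgeR adjusted p = 0.139) and DDIT3 (-0.10 ± 0.05, adjusted p = 0.071) did not pass, while TRIB3 was higher by 0.51 ± 0.04 and HSPA5 lower (-0.15 ± 0.02). These are means over 5 times, and those of ATF4, DDIT3 and HSPA5 cover differences of both signs, which were not tested at single times. ATF4 was at 330.5 ± 1.37 CPM in Dmr-PERK and 271.5 ± 7.5 in Parental cells at 0 h but at 325.1 ± 4.24 and 392.8 ± 9.34 at 16 h (SD, n = 3 each). DDIT3 was at 27.8 ± 1.38 and 37.9 ± 3.52 CPM at 0 h but 7.71 ± 0.283 and 6.88 ± 0.449 at 8 h, and HSPA5 at 680.1 ± 32.2 and 898.4 ± 52.7 at 0 h but 647.1 ± 10.8 and 572.2 ± 7.46 at 16 h. In all, edgeR called 16876 of 26998 genes, 8185 higher and 8691 lower (17369 without the libraries that stood apart), 2943 of them by at least 2-fold.

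Of 20 p53 targets, 18 were higher and 2 lower in Dmr-PERK cells (median log2 difference 0.41, camera adjusted p = 2.65e-05 with an estimated correlation). Of 15 hypoxia and glycolysis genes 13 were higher and 2 lower (median 0.405, adjusted p = 0.00846). Interferon-stimulated genes were higher in 12 and lower in 2 of 17 (adjusted p = 0.0715 with an estimated correlation). Matrix genes were lower in 13 and higher in 5 of 20 (adjusted p = 0.0915 with an estimated correlation), and ER chaperones lower in 15 and higher in 2 of 18 (adjusted p = 0.237 with an estimated correlation). ATF4/CHOP targets were divided, 12 higher, 12 lower and 5 not past the threshold. Adjusted over the list alone, these counts were the same.

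The first question of the design is what dimerization of Dmr-PERK does without another stress. With dimerizer, transcripts of the integrated stress response, the program that follows eIF2α phosphorylation, rose in Dmr-PERK cells. ATF4 (ENSG00000128272.14, chromosome 22, 39519695 to 39522685), its central transcription factor, rose from 331.4 ± 19.0 to 692.4 ± 33.0 CPM (SD, n = 12 each), a log2 fold change of 1.06 ± 0.02. DDIT3 (ENSG00000175197.11), which encodes CHOP, rose from 9.31 ± 1.58 to 82.1 ± 5.43 CPM (3.15 ± 0.04), and ASNS (ENSG00000070669.16, chromosome 7, 97852118 to 97872542), asparagine synthetase, from 65.6 ± 5.11 to 339.4 ± 95.7 CPM (2.32 ± 0.02). TRIB3 (ENSG00000101255.10, chromosome 20, 362835 to 397559), a pseudokinase, rose from 32.3 ± 6.30 to 355.6 ± 60.9 CPM (3.46 ± 0.03). CHAC1, which degrades glutathione, rose by 3.37 ± 0.05, SESN2 by 2.45 ± 0.04 and PPP1R15A (GADD34), a subunit of the eIF2α phosphatase, by 2.26 ± 0.03. Of 29 ATF4/CHOP targets tested, 27 rose and 2 fell (median 2.22, camera adjusted p = 2.77e-07 with an estimated correlation).

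**Figure D2:**
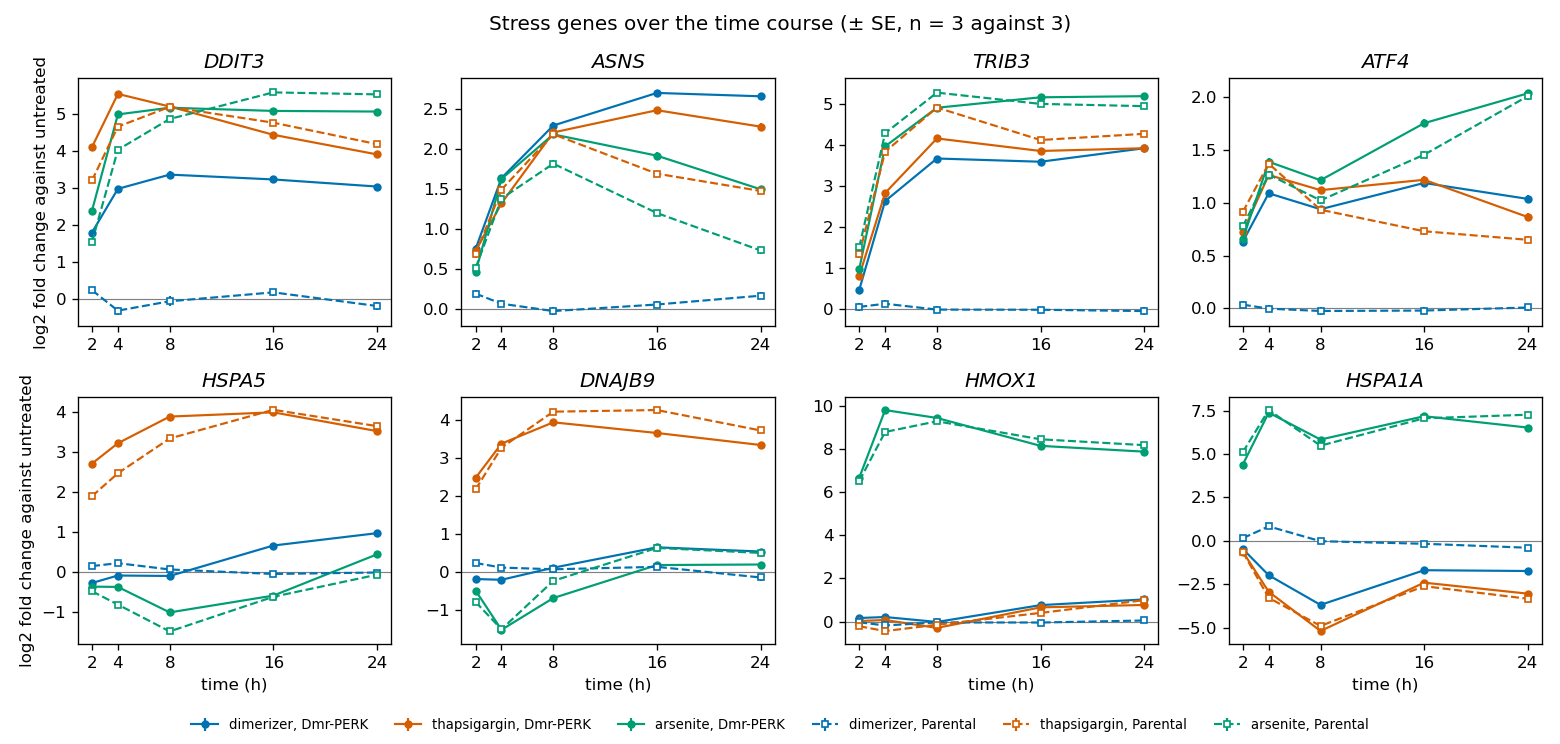
Log2 fold change against untreated wells (± SE) of 8 genes over 2 to 24 h, for dimerizer, thapsigargin and arsenite in both lines, with 2 h set against untreated 0 h. With dimerizer, DDIT3 in Dmr-PERK cells lies between 1.80 and 3.36, while HSPA5 passes from -0.28 to 0.97.

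Genes of amino acid supply moved the same way with dimerizer. Of 12 serine and one-carbon enzymes 7 rose, 3 fell and 2 did not pass (median 0.96, adjusted p = 0.033 with an estimated correlation), led by PSAT1 (1.75 ± 0.02), MTHFD2 (1.49 ± 0.02) and PHGDH (1.20 ± 0.02). Of 20 cytosolic tRNA synthetases 18 rose and 1 fell (median 0.74, adjusted p = 0.00397), with SARS at 1.56 ± 0.02, GARS at 1.44 ± 0.02 and CARS at 1.37 ± 0.02. Of 14 amino acid transporters 10 rose and 3 fell (median 1.11, adjusted p = 0.00761), among them SLC7A11 (2.13 ± 0.03), the cystine transporter, SLC6A9 (1.73 ± 0.03) and SLC1A5 (1.35 ± 0.02). Ribosome biogenesis genes rose in 22 of 23 and fell in 0 (median 0.475, adjusted p = 0.0368), with RRP12 at 0.90 ± 0.02, POLR1B at 0.84 ± 0.02 and DDX21 at 0.75 ± 0.02.

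The largest rises with dimerizer among genes of at least 5 CPM in the higher group, the limit set for largest rises and falls throughout, were outside these groups. TSLP (ENSG00000145777.14, chromosome 5, 111070062 to 111078024), an epithelial cytokine, rose from 0.384 ± 0.140 to 9.23 ± 5.75 CPM (4.25 ± 0.11). SPX rose from 6.95 ± 1.79 to 141 ± 87.1 CPM (4.01 ± 0.04). RAB39B (3.87 ± 0.04), STC2 (3.67 ± 0.09), OLAH (3.67 ± 0.14) and VIP (3.56 ± 0.08) rose too. DRD1, a dopamine receptor, fell (-3.08 ± 0.12), as did IGFBP5 (-2.91 ± 0.10), NYNRIN (-2.57 ± 0.06), MIAT (-2.56 ± 0.06), C10orf10 (-2.54 ± 0.08) and CXCL14 (-2.52 ± 0.13). NF-kB and inflammatory genes rose in 14 and fell in 1 of 18 (median 0.67, adjusted p = 0.0368 with an estimated correlation), with RELB at 1.38 ± 0.04, NFKB2 at 0.85 ± 0.03 and IL1A at 3.03 ± 0.11.

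Heat shock, cholesterol and interferon genes fell with dimerizer. HSPA1A (ENSG00000204389.9, chromosome 6, 31815464 to 31817946), the inducible cytosolic HSP70, was at 55.7 ± 36.0 CPM against 251.7 ± 117.1 untreated (-2.27 ± 0.05). HSPA8 (-1.23 ± 0.02) and CRYAB (-1.33 ± 0.03) fell too. Of 20 HSF1 heat shock genes 19 fell and 0 rose by edgeR (median -0.62, adjusted p = 0.0178 with an estimated correlation). Of 23 cholesterol synthesis genes 22 fell and 1 rose (median -0.71, adjusted p = 0.00114), among them STARD4 (-1.42 ± 0.03). Interferon-stimulated genes fell in 15 of 17 and rose in 0 by edgeR (median -0.71, adjusted p = 0.00422), with OAS3 at -0.97 ± 0.05, IFIT1 at -2.07 ± 0.10 and PARP9 at -0.71 ± 0.04.

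ER chaperones did not rise as a group with dimerizer. CALR (-0.46 ± 0.01), HSP90B1 (-0.43 ± 0.02) and MANF (-0.70 ± 0.03) fell. The list held 14 that fell, 2 that rose and 2 not past the threshold (median -0.24, adjusted p = 0.245 with an estimated correlation). HSPA5 (BiP, ENSG00000044574.7, chromosome 9, 125234853 to 125241330), the main ER chaperone, was at 976.4 ± 97.4 CPM against 779.2 ± 189.2 (0.36 ± 0.02). It did not pass at 4 h (-0.09 ± 0.04, edgeR adjusted p = 0.0772), was lower at 8 h (-0.10 ± 0.04, adjusted p = 0.0377) and was higher at 16 and 24 h. The later comparison is with a lower untreated level (995.4 ± 30.8 CPM at 4 h and 647.1 ± 10.8 at 16 h). HERPUD1 rose by 1.20 ± 0.03 and DNAJB9 by 0.28 ± 0.04 (lower at 4 h by -0.20 ± 0.07 and higher at 16 h by 0.655 ± 0.072). XBP1-type genes were divided, 12 up and 10 down of 24 (median 0.03, adjusted p = 0.616), with XBP1 at 1.52 ± 0.02 and GFPT1 at 0.78 ± 0.02. NRF2 antioxidant genes were divided as well, 12 up and 8 down of 26 (median 0.045, adjusted p = 0.462), with SRXN1 at 0.82 ± 0.02, PRDX1 at -0.90 ± 0.02, GCLM at 0.53 ± 0.03 (-0.02 ± 0.05 at 4 h and 1.22 ± 0.05 at 24 h) and HMOX1 (ENSG00000100292.16, chromosome 22, 35380361 to 35394214) at 0.50 ± 0.05.

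In the remaining lists the calls with dimerizer were as follows, and none passed with an estimated correlation. Mitosis genes fell in 18 and rose in 0 of 20 by edgeR (median -0.26, adjusted p = 0.113 with an estimated correlation), with KIF20A at -0.82 ± 0.03, and DNA replication genes fell in 19 and rose in 1 of 24 (median -0.18, adjusted p = 0.282), with PCNA at -0.75 ± 0.03. Immediate early genes rose in 12 and fell in 2 of 18 (median 0.285, adjusted p = 0.169), with MYC at 1.69 ± 0.03 and DUSP1 at 0.88 ± 0.04. Mitochondrially encoded genes fell in 11 of 13 (median -0.22, adjusted p = 0.486), with MT-ND6 at -0.34 ± 0.03. Matrix genes fell in 15 and rose in 3 of 20 (median -0.40, adjusted p = 0.0982), with THBS1 at -1.35 ± 0.03. Autophagy genes rose in 11 and fell in 3 of 16 (median 0.25, adjusted p = 0.055), with MAP1LC3B at 1.25 ± 0.02. In the eIF2 pathway 10 rose and 4 fell (median 0.23, adjusted p = 0.0873), with EIF2S2 at 0.71 ± 0.03. Of 12 housekeeping genes 9 fell and 3 rose (median -0.23, adjusted p = 0.282), with ACTB at -0.61 ± 0.02.

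The p53 targets (12 up and 7 down of 20, adjusted p = 0.237 with an estimated correlation), ribosomal proteins (38 up and 11 down of 74, adjusted p = 0.873), metallothioneins (1 up and 3 down of 8, adjusted p = 0.536), hypoxia genes (3 up and 9 down of 15, adjusted p = 0.396), construct genes (0 up and 2 down of 2 by edgeR, adjusted p = 0.114), epithelial markers (1 up and 5 down of 11, adjusted p = 0.282), blood markers (0 up and 1 down of 6 by edgeR, adjusted p = 0.742) and osteoblast markers (2 up and 3 down of 6, adjusted p = 0.494) were called by neither form of camera. GDF15 (2.22 ± 0.05), VEGFA (1.67 ± 0.02), LDHA (-0.67 ± 0.02), RPL12 (0.35 ± 0.02), RPL7A (-0.43 ± 0.03) and MT1E (-0.51 ± 0.03) stand for them. The epithelial regulator ESRP1, below that limit of 5 CPM, rose from 0.0549 to 3.31 CPM (15 and 894 counts, 5.77 ± 0.23) while KRT8 (-0.40 ± 0.02) fell. The blood markers had a median of -0.30, a mean of 0.03 and a test direction down. The counts with dimerizer were the same for 25 lists adjusted over the list alone, while p53 targets had 13 up, ribosomal proteins 12 down and mitochondrially encoded genes 13 down. In all, edgeR called 14901 of 26998 genes, 7415 up and 7486 down (15312 without the libraries that stood apart). By at least 2-fold it called 2070 of them, 747 up and 1323 down. None of the 28 medians changed sign under another scaling.

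Parental cells, which lack the construct, were given the same dimerizer. ATF4 (-0.01 ± 0.02, edgeR adjusted p = 0.947), DDIT3 (-0.09 ± 0.06, adjusted p = 0.709), ASNS (0.06 ± 0.02, adjusted p = 0.221) and TRIB3 (0.01 ± 0.04, adjusted p = 1) did not pass the test over 4 to 24 h, nor did any other gene of the fixed panel. At 4 h alone HSPA1A (0.84 ± 0.10), SESN2 (0.435 ± 0.092) and HSPA5 (0.22 ± 0.04) were higher and HERPUD1 lower (-0.30 ± 0.05), and at 2 h HERPUD1 (0.25 ± 0.05) and ASNS (0.19 ± 0.04) were higher, by edgeR. The lowest called genes were ENPP1 (-0.43 ± 0.05), TNFRSF11B (-0.36 ± 0.06), DUSP2 (-0.33 ± 0.07), MMP13 (-0.31 ± 0.07) and RGS4 (-0.31 ± 0.08). The highest were RAC3 (0.28 ± 0.06), OXTR (0.25 ± 0.06), TOX (0.23 ± 0.05), HOXA13 (0.22 ± 0.04) and TRABD2B (0.21 ± 0.05). Of 29 ATF4/CHOP targets 0 passed in edgeR, and 1 higher and 2 lower passed adjusted over the list alone (median 0.01, adjusted p = 0.873 with an estimated correlation). No list held with an estimated correlation, the lowest adjusted p being 0.0938 for mitosis (2 up of 20, 4 adjusted over the list alone). HSF1 heat shock genes (0 of 20 by edgeR, median 0.04) passed camera with the preset correlation and had an adjusted p = 0.134 with an estimated correlation.

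The Parental dimerizer comparison had 157 calls, 88 up and 69 down. It rested on 4 h, where 2029 genes were called, while edgeR called 48 at 2 h (6220 against untreated 4 h) and 0 at 8, 16 and 24 h (1115, 1369 and 1399 genes at an unadjusted p under 0.05; DESeq2 called 2, 0 and 12). Over 8, 16 and 24 h alone, a mean chosen after seeing the data, edgeR called 0 genes (1356 at an unadjusted p under 0.05). DESeq2 called 282, and 384 were called without the libraries that stood apart, 4 without replicate 2 of every group. The direction of the calls also moved with the processing, with 201 up and 81 down by DESeq2, 34 up and 60 down without a filter, 11 up and 17 down on log2(TPM + 1), 6 up and 8 down on log2(TPM + 0.1), and 1 up and 3 down without replicate 2. At 2 h DESeq2 called 40 up and 38 down.

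The difference between the lines in the dimerizer effect was tested directly. ATF4 (1.08 ± 0.02), DDIT3 (3.24 ± 0.07), ASNS (2.26 ± 0.03), TRIB3 (3.45 ± 0.05) and CHAC1 (3.44 ± 0.09) responded more in Dmr-PERK cells (log2 differences). So did TSLP (4.20 ± 0.20), SPX (4.00 ± 0.13), RAB39B (3.87 ± 0.07), VIP (3.77 ± 0.24) and OLAH (3.74 ± 0.29). PCDH18 (-3.22 ± 0.21), DRD1 (-3.16 ± 0.14), IGFBP5 (-2.89 ± 0.13), SOX2 (-2.68 ± 0.15), CXCL14 (-2.62 ± 0.14) and HSPA1A (-2.34 ± 0.07) had lower responses there. Called with an estimated correlation were ATF4/CHOP targets (27 higher, 1 lower of 29, median 2.16, adjusted p = 1.6e-08), tRNA synthetases (18 and 1 of 20, adjusted p = 0.00202), transporters (10 and 2 of 14, adjusted p = 0.00263), serine and one-carbon enzymes (7 and 3 of 12, adjusted p = 0.0119), cholesterol synthesis (1 and 21 of 23, median -0.67, adjusted p = 0.000658), interferon-stimulated genes (0 and 15 of 17, adjusted p = 0.00517), HSF1 genes (0 and 18 of 20, adjusted p = 0.0082), NF-kB genes (14 and 1 of 18, adjusted p = 0.0279) and ribosome biogenesis (22 and 0 of 23, adjusted p = 0.0309). These counts were the same adjusted over the list alone, except HSF1 genes, 19 lower, and ribosome biogenesis, 23 higher. In all 12678 genes differed, 6412 with a higher and 6266 with a lower response in Dmr-PERK cells (13187 without the libraries that stood apart).

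The response to dimerizer was followed over time as log2 fold changes against time-matched untreated wells, with 2 h set against untreated 0 h. In Dmr-PERK cells DDIT3 had log2 fold changes of 1.80 ± 0.07 at 2 h, 2.98 ± 0.08 at 4 h, 3.36 ± 0.09 at 8 h, 3.23 ± 0.09 at 16 h and 3.04 ± 0.08 at 24 h. ASNS had 0.75, 1.63, 2.29, 2.70 and 2.65 (each ± 0.04), and CHAC1 had its largest fold change at 4 h (4.04 ± 0.11). HSPA5 was lower at 2 h (-0.28 ± 0.04) and 8 h (-0.10 ± 0.04) and higher at 16 h (0.66 ± 0.04) and 24 h (0.97 ± 0.04). Its untreated level fell meanwhile, as given above (n = 3 each). HSPA1A had its lowest fold change at 8 h (-3.68 ± 0.11). These fold changes are not the course of the levels, since the untreated wells changed as well. At 0, 4 and 8 h untreated DDIT3 was at 27.8, 10.7 and 7.71 CPM and CHAC1 at 8.02, 4.18 and 6.61. HSPA1A was at 89.1, 85.2 and 353.3 CPM in the same wells. The effect changed between 4 and 24 h for 11353 genes with dimerizer, 14096 with thapsigargin and 19219 with arsenite (edgeR F-test).

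Genes called with dimerizer numbered 4767 at 2 h against untreated 0 h, then 8144, 9993, 11652 and 12986 at 4, 8, 16 and 24 h against time-matched wells. With thapsigargin they numbered 8972, 10686, 13335, 13896 and 14851, and with arsenite 5381, 13253, 18194, 21276 and 21995. In Parental cells thapsigargin gave 7870, 10963, 13410, 15169 and 14747 and arsenite 4980, 13282, 16239, 21279 and 21722. The counts at 2 h depend on the control: against untreated 4 h they were 9000 with dimerizer, 11405 with thapsigargin and 9353 with arsenite in Dmr-PERK cells, and 6220, 10502 and 9326 in Parental cells. At 2 h with dimerizer 2303 rose and 2464 fell, but 2985 rose and 1793 fell with library totals alone. For Parental arsenite 2832 rose and 2148 fell at 2 h (2337 and 2867 with library totals), and 6500 rose and 6782 fell at 4 h (5418 and 8608).

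**Figure D3:**
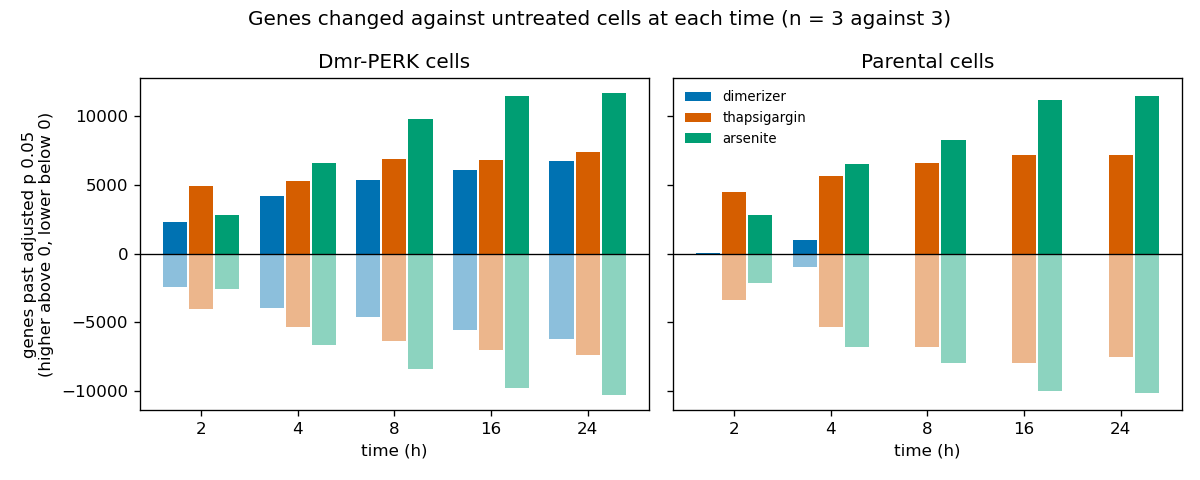
Number of genes called by edgeR at 2, 4, 8, 16 and 24 h per treatment and line, with full bars for higher and pale bars for lower genes and 2 h set against untreated 0 h. Dimerizer in Dmr-PERK cells has 4767 genes at 2 h (9000 against untreated 4 h) and 12986 at 24 h, and in Parental cells only 2 h (48, or 6220 against untreated 4 h) and 4 h (2029) have calls.

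Thapsigargin was used as a stress that reaches PERK through the ER. In Dmr-PERK cells it raised HSPA5 from 779.2 ± 189.2 to 9811 ± 2631 CPM (SD, n = 12 each), a log2 fold change of 3.65 ± 0.02, together with HYOU1 (2.74 ± 0.02), DNAJB11 (2.19 ± 0.02), DNAJB9 (3.58 ± 0.03), SEC24D (2.45 ± 0.02), SEL1L (2.37 ± 0.02) and HERPUD1 (3.25 ± 0.03), which act in folding, transport and degradation of ER proteins. All 18 ER chaperones rose (median 1.63, camera adjusted p = 0.00194 with an estimated correlation), and 23 of 24 XBP1-type genes rose and 1 fell (median 1.29, adjusted p = 3.41e-07). Integrated stress response genes rose as well, with DDIT3 at 4.76 ± 0.04 (278.6 ± 139.8 CPM), TRIB3 at 3.70 ± 0.03, CHAC1 at 3.00 ± 0.05, PPP1R15A at 2.99 ± 0.03, SESN2 at 2.37 ± 0.04, ASNS at 2.07 ± 0.02 and ATF4 at 1.12 ± 0.02. Of 29 ATF4/CHOP targets 27 rose and 2 fell (median 2.07, adjusted p = 2.95e-05).

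The largest rises with thapsigargin were those of SPRR2D, with 2 counts in the 12 untreated libraries and 4476 in the treated ones, KLHDC7B (6.77 ± 0.22), FIBIN (5.44 ± 0.17) and the near-identical CLUHP10 (6.83 ± 0.19), CLUHP5 (6.74 ± 0.24) and CLUHP4 (6.67 ± 0.19). The largest falls were those of DRD1 (-4.87 ± 0.16), LHX1 (-4.81 ± 0.15), SDPR (-4.29 ± 0.09), TET1 (-4.20 ± 0.13), EDN2 (-4.12 ± 0.14) and RP11-466H18.1, a pseudogene with 0 counts in the 12 treated libraries, at least 716-fold lower. tRNA synthetases (17 up, 1 down of 20, adjusted p = 0.0294 with an estimated correlation; WARS 2.27 ± 0.03), transporters (10 up, 1 down of 14, adjusted p = 0.0294; SLC7A11 2.62 ± 0.03) and autophagy genes (11 up, 1 down of 16, adjusted p = 0.0381; WIPI1 2.45 ± 0.03) rose. HSF1 genes (0 up by edgeR, 18 down of 20, adjusted p = 0.0368; HSPA1A -3.38 ± 0.06), mitosis genes (0 up by edgeR, 19 down of 20, adjusted p = 0.0425; MKI67 -1.07 ± 0.03), interferon-stimulated genes (0 up by edgeR, 14 down of 17, adjusted p = 0.0159; OAS3 -1.47 ± 0.05) and matrix genes (3 up, 16 down of 20, adjusted p = 0.0408; TGFBI -2.92 ± 0.05) fell. So did, on average over 4 to 24 h, counts of EIF2AK3 (-0.58 ± 0.02) and FKBP1A (-0.52 ± 0.02, list adjusted p = 0.0408). Both can be reads of 1 construct.

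Lists whose calls with thapsigargin did not hold with an estimated correlation were serine and one-carbon enzymes (7 up, 4 down of 12, adjusted p = 0.179 with an estimated correlation), cholesterol synthesis (18 up, 4 down of 23, adjusted p = 0.196), DNA replication (1 up, 23 down of 24, adjusted p = 0.0847), ribosomal proteins (12 up, 41 down of 74, adjusted p = 0.824), ribosome biogenesis (16 up, 5 down of 23, adjusted p = 0.279), mitochondrially encoded genes (0 up by edgeR, 13 down of 13, adjusted p = 0.402), NF-kB genes (12 up, 1 down of 18, adjusted p = 0.105) and housekeeping genes (3 up, 9 down of 12, adjusted p = 0.166). Their members included ALDH1L2 (2.74 ± 0.04), STARD4 (1.44 ± 0.03), CDC6 (1.62 ± 0.02), the licensing factor that alone rose among the replication genes, MCM4 (-1.22 ± 0.02), IL1A (5.39 ± 0.08), CXCL8 (4.81 ± 0.11) and ACTB (-1.31 ± 0.02). Called by neither form of camera were NRF2 genes (12 up, 13 down of 26, adjusted p = 0.908; median -0.04, mean 0.03, test down), metallothioneins (1 up, 4 down of 8), immediate early genes (9 up, 6 down of 18), p53 targets (11 up, 7 down of 20), hypoxia genes (5 up, 8 down of 15), the eIF2 pathway (9 up, 4 down of 14), epithelial (1 up, 5 down of 11), blood (0 up by edgeR, 2 down of 6; median 0.085, mean -0.09, test down) and osteoblast markers (1 up, 4 down of 6). The counts with thapsigargin were the same adjusted over the list alone, except 13 ribosomal proteins up. In all 17020 genes were called, 8338 up and 8682 down (17367 without the libraries that stood apart), 3915 of them by at least 2-fold.

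Parental cells responded to thapsigargin too. HSPA5 rose by 3.37 ± 0.02 (854.6 ± 311.2 to 8391 ± 1067 CPM, n = 12 each), DNAJB9 by 3.87 ± 0.03, HERPUD1 by 3.46 ± 0.03, DDIT3 by 4.69 ± 0.04, TRIB3 by 4.29 ± 0.04, ASNS by 1.71 ± 0.02 and ATF4 by 0.92 ± 0.02. HSPA1A fell (-3.52 ± 0.06). SPRR2D (8.34 ± 0.39), KLHDC7B (7.31 ± 0.17), CLUHP4 (6.86 ± 0.11), ESRP1 (6.85 ± 0.14) and DUX4L25 (6.48 ± 0.44) had the largest rises. LHX1 (-5.54 ± 0.14), DRD1 (-4.86 ± 0.12), LRRC15 (-4.69 ± 0.22), CXCL14 (-4.65 ± 0.09) and EDN2 (-4.65 ± 0.11) had the largest falls. ER chaperones (18 up of 18, adjusted p = 0.00146 with an estimated correlation) and XBP1-type genes (23 up, 1 down of 24, adjusted p = 2.64e-07) rose. So did ATF4/CHOP targets (28 up, 1 down of 29, adjusted p = 2.95e-05) and tRNA synthetases (18 up, 1 down of 20, adjusted p = 0.0213). Cholesterol synthesis (19 up, 2 down of 23, adjusted p = 0.0395) and EIF2AK3 with FKBP1A (2 up of 2, median 1.35, adjusted p = 0.00846) rose. Mitosis genes (20 down of 20, adjusted p = 0.0404) fell. HSF1 genes had 18 down of 20 (adjusted p = 0.0709 with an estimated correlation). Adjusted over the list alone, these counts were the same. In all 17571 genes were called, 8124 up and 9447 down (17970 without the libraries that stood apart).

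The test of the line difference in the thapsigargin effect called 6939 genes, 3054 with a higher and 3885 with a lower response in Dmr-PERK cells. That split turned with the scaling, with 4010 higher and 3040 lower with library totals alone, 3486 and 2114 on log2(TPM + 1) and 3103 and 1925 on log2(TPM + 0.1), and 4581 genes were called without replicate 2 of every group. EIF2AK3 differed by -2.76 ± 0.03 on average over 4 to 24 h. Its counts in Dmr-PERK cells can hold reads of the construct, so whether the gene itself responded differently cannot be told. In Parental cells it had log2 fold changes of 1.76 to 2.41 between 2 and 24 h. In Dmr-PERK cells it was slightly higher at 2 h (0.11 ± 0.04, edgeR adjusted p = 0.034), did not pass at 4 h (-0.03 ± 0.04, adjusted p = 0.648) and was lower from 8 h (-0.47 ± 0.04). MYOCD (2.82 ± 0.39), NTRK3 (2.44 ± 0.10), CXCL8 (2.14 ± 0.28), MMP3 (1.88 ± 0.11) and FMN1 (1.82 ± 0.06) responded more in Dmr-PERK cells. PTX3 (-2.13 ± 0.11), STK32A (-2.05 ± 0.15) and GDF15 (-2.02 ± 0.11) responded less. So did RP11-466H18.1, for which no fold is given since it had 0 counts in treated Dmr-PERK cells. ATF4 differed by 0.20 ± 0.02, ASNS by 0.36 ± 0.03, TRIB3 by -0.60 ± 0.05, HSPA5 by 0.28 ± 0.03 and DNAJB9 by -0.29 ± 0.04, while DDIT3 did not pass (0.07 ± 0.06, edgeR adjusted p = 0.473). The means of DDIT3, HSPA5, DNAJB9, ASNS and ATF4 cover differences of both signs, which were not tested at single times. DDIT3 had log2 fold changes of 5.53 ± 0.08 in Dmr-PERK and 4.65 ± 0.07 in Parental cells at 4 h but 4.43 ± 0.08 and 4.76 ± 0.07 at 16 h. HSPA5 had 3.21 ± 0.04 and 2.46 ± 0.04 at 4 h but 3.51 ± 0.04 and 3.64 ± 0.04 at 24 h, and DNAJB9 3.38 ± 0.05 and 3.27 ± 0.05 but 3.34 ± 0.06 and 3.72 ± 0.06. ASNS had 1.32 ± 0.04 and 1.49 ± 0.04 at 4 h but 2.27 ± 0.04 and 1.47 ± 0.04 at 24 h, and ATF4 1.264 ± 0.035 and 1.371 ± 0.035 but 0.865 ± 0.034 and 0.649 ± 0.034. Over 8, 16 and 24 h, a mean chosen after seeing the data, the DDIT3 difference was -0.198 (edgeR adjusted p = 0.0368). Cholesterol synthesis (1 higher, 21 lower of 23, median -0.30, adjusted p = 0.000542 with an estimated correlation), hypoxia genes (0 and 10 of 15, adjusted p = 0.00263), XBP1-type genes (1 and 14 of 24, median -0.12, adjusted p = 0.00599) and metallothioneins (0 and 3 of 8, adjusted p = 0.0377) responded less, and NF-kB genes (8 and 1 of 18, adjusted p = 0.0498) more. Hypoxia genes had 12 lower, XBP1-type genes 15 lower and NF-kB genes 9 higher adjusted over the list alone. ATF4/CHOP targets had 14 higher and 8 lower of 29 (adjusted p = 0.396 with an estimated correlation), 15 higher adjusted over the list alone.

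From 4 h on arsenite was the stress with the most calls in both lines, while at 2 h thapsigargin had more. In Dmr-PERK cells HMOX1, heme oxygenase, rose from 26.1 ± 6.40 to 12230 ± 4856 CPM (8.81 ± 0.04) and HSPA1A from 251.7 ± 117.1 to 24470 ± 8015 CPM (6.73 ± 0.05; SD, n = 12 each). HSPA6 (11.49 ± 0.09), HSPA7 (10.96 ± 0.12), XRCC6P1 (1 count untreated and 7144 treated), MT1H (2 and 3551) and CD300LB (10.05 ± 0.13) had the largest rises. ATP13A4-AS1 was at least 3340-fold higher from 0 counts in 12 untreated libraries. The largest falls were those of DRD1 (-5.67 ± 0.16), TRIL (-4.74 ± 0.12), MAGEE1 (-4.66 ± 0.10), NOG (-4.28 ± 0.06), KIF18B (-4.20 ± 0.05) and CCL2 (-4.18 ± 0.17). All 20 HSF1 genes (median 2.38, camera adjusted p = 0.0188 with an estimated correlation; DNAJB1 4.51 ± 0.03, BAG3 3.82 ± 0.03) and all 8 metallothioneins and zinc exporters rose (median 4.64, adjusted p = 0.00237; MT1X 5.06 ± 0.03). ATF4/CHOP targets rose in 28 and fell in 1 of 29 (median 2.32, adjusted p = 0.00146), with PPP1R15A at 5.33 ± 0.03, DDIT3 at 5.07 ± 0.04, TRIB3 at 4.82 ± 0.04, CTH at 4.70 ± 0.04, SESN2 at 3.48 ± 0.04, CHAC1 at 3.22 ± 0.05, ASNS at 1.80 ± 0.02 and ATF4 at 1.60 ± 0.02. Transporters rose in 13 and fell in 1 of 14 (adjusted p = 0.0377; SLC7A11 3.07 ± 0.03).

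On average over 4 to 24 h of arsenite HSPA5 (-0.38 ± 0.02), DNAJB9 (-0.45 ± 0.04) and PDIA4 (-1.74 ± 0.04) fell, though XBP1 (2.24 ± 0.02) and HERPUD1 (1.34 ± 0.03) rose. HSPA5 was lowest at 8 h (-1.01 ± 0.04) and higher than untreated at 24 h (0.44 ± 0.04). DNAJB9 was lowest at 4 h (-1.51 ± 0.09) and higher at 16 h (0.19 ± 0.07, edgeR adjusted p = 0.0148) and 24 h (0.20 ± 0.08, adjusted p = 0.0109). ER chaperones had 3 up and 15 down of 18 (median -0.46, adjusted p = 0.265 with an estimated correlation) and XBP1-type genes 9 up and 14 down of 24 (adjusted p = 0.488). Mitosis genes fell in 19 and rose in 1 of 20 (median -1.395, adjusted p = 0.0377), with KIF20A at -2.99 ± 0.04. DNA replication genes fell in 21 and rose in 2 of 24 (median -1.65, adjusted p = 0.114), with MCM3 at -3.01 ± 0.04. NRF2 genes rose in 18 and fell in 6 of 26 (median 0.53, adjusted p = 0.122 with an estimated correlation), with GCLM at 2.86 ± 0.02 and SQSTM1 at 2.27 ± 0.02. Immediate early genes (12 up, 6 down of 18, adjusted p = 0.377; FOS 4.65 ± 0.05), cholesterol synthesis (4 up, 19 down of 23, adjusted p = 0.146), interferon-stimulated genes (2 up, 15 down of 17, adjusted p = 0.0576; PARP9 -2.97 ± 0.06), tRNA synthetases (13 up, 6 down of 20, adjusted p = 0.353; CARS 2.03 ± 0.02), ribosome biogenesis (2 up, 19 down of 23, adjusted p = 0.282; RRS1 -2.77 ± 0.05), matrix genes (6 up, 14 down of 20, adjusted p = 0.31; COL4A1 -1.92 ± 0.05) and autophagy genes (13 up, 3 down of 16, adjusted p = 0.08; GABARAPL1 2.60 ± 0.03) also lost their call with an estimated correlation.

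Mitochondrially encoded genes fell in 11 of 13 with arsenite (median -0.325, adjusted p = 0.514 with an estimated correlation; MT-ATP6 -0.997 ± 0.036). In replicate 3 at 4 h all 13 lay below both other replicates, by a median of -0.91. Called by neither form of camera were serine enzymes (7 up, 5 down of 12), p53 targets (7 up, 13 down of 20), hypoxia genes (10 up, 4 down of 15), epithelial (6 up, 5 down of 11), blood (3 up of 6; median 1.72, adjusted p = 0.179) and osteoblast markers (4 up, 2 down of 6), and NF-kB genes (10 up, 8 down of 18; median 0.56, mean 0.25, test down). So were ribosomal proteins (18 up, 29 down of 74, median -0.03 but 0.085 with size factors), the eIF2 pathway (6 up, 7 down of 14, median -0.11 but 0.003 with size factors; mean 0.36, test down), housekeeping genes (3 up, 7 down of 12, median -0.05 but 0.06 with size factors; mean 0.10, test down) and the construct genes (2 up of 2, median 0.15 but -0.04 with library totals). The counts with arsenite were the same adjusted over the list alone. In all 22559 genes were called, 11979 up and 10580 down (22808 without the libraries that stood apart), 10677 of them by at least 2-fold. The median of all genes was 0.12 with TMM, 0.22 with DESeq2 size factors, -0.075 with library totals and -0.03 and -0.06 on log2 TPM, so arsenite changes are relative to that shift.

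**Figure D4:**
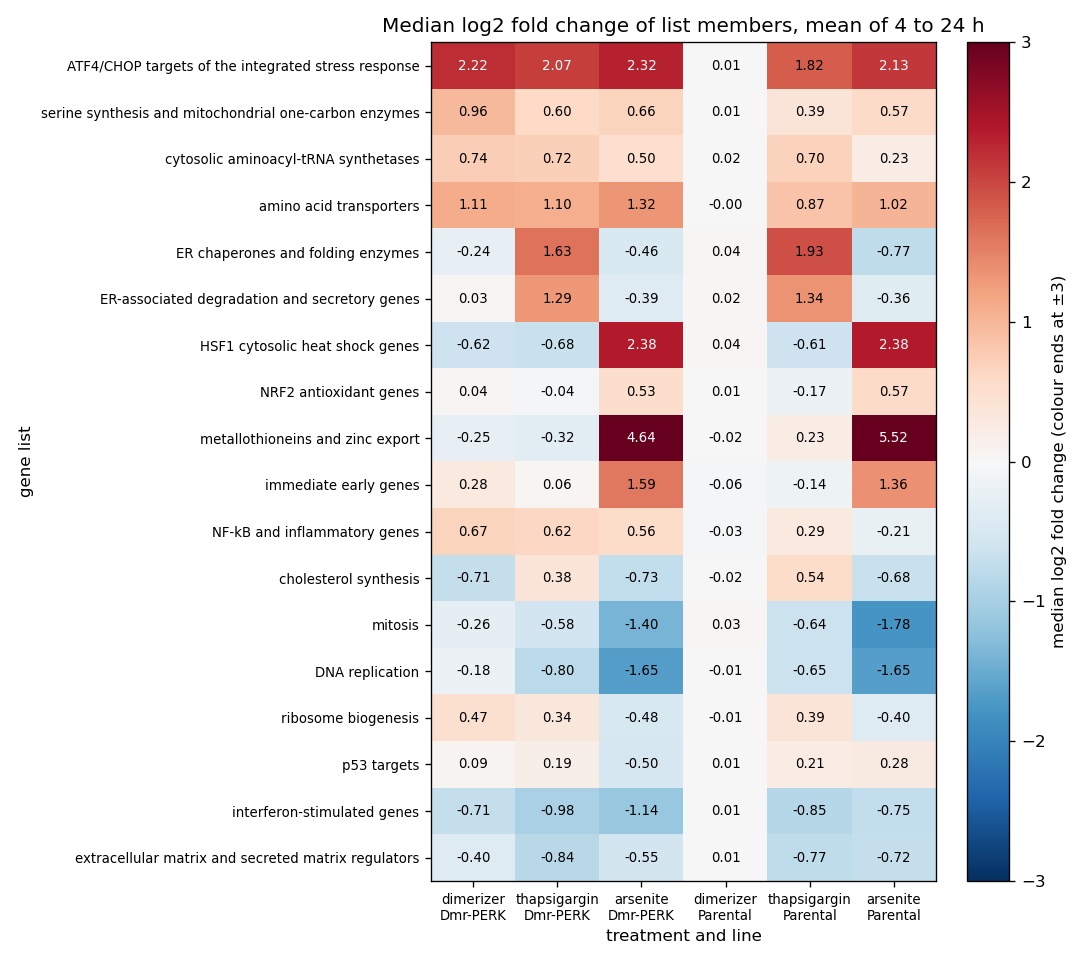
Median log2 fold change of 18 gene lists (lists down, comparisons across, mean of 4, 8, 16 and 24 h) for each treatment in each line, with colors that end at 3 in either direction. ATF4/CHOP targets stand at 2.22, 2.07 and 2.32 in Dmr-PERK cells, ER chaperones at -0.24, 1.63 and -0.46 and HSF1 genes at -0.62, -0.68 and 2.38 with dimerizer, thapsigargin and arsenite, and none of these turns under another scaling.

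In Parental cells arsenite raised HMOX1 by 8.67 ± 0.04 (27.3 ± 3.43 to 11730 ± 4269 CPM, n = 12 each), HSPA1A by 6.84 ± 0.05, PPP1R15A by 5.44 ± 0.03, DDIT3 by 5.00 ± 0.04, TRIB3 by 4.89 ± 0.04, ATF4 by 1.44 ± 0.02 and ASNS by 1.28 ± 0.02. HSPA5 fell (-0.75 ± 0.02) but did not pass at 24 h (-0.07 ± 0.04, edgeR adjusted p = 0.106). HSPA6 (12.61 ± 0.10), CD300LB (11.06 ± 0.10), HSPA7 (10.45 ± 0.12), MYCT1 (9.79 ± 0.09) and TDRG1 (9.69 ± 0.37) rose most. TRIL (-4.72 ± 0.10), DRD1 (-4.31 ± 0.11), KIF18B (-4.16 ± 0.05), PIF1 (-3.99 ± 0.05) and CCL2 (-3.94 ± 0.24) fell most. In replicate 3 at 24 h CCL2 was at 5.16 CPM against 0.183 in the other replicates, and mitochondrially encoded genes were lower by a median of -0.69. ATF4/CHOP targets (29 up of 29, adjusted p = 0.000647 with an estimated correlation), HSF1 genes (19 up of 20, adjusted p = 0.0142) and metallothioneins (8 up of 8, adjusted p = 0.00128) rose and mitosis genes (1 up, 19 down of 20, adjusted p = 0.0224) fell. Ribosomal proteins had 63 up and 2 down of 74 (adjusted p = 0.713 with an estimated correlation), but their median of 0.16 turned to -0.025 with library totals. Mitochondrially encoded genes had 8 up and 5 down of 13 (adjusted p = 0.962), a median of 0.18 that was -0.01 with library totals. Adjusted over the list alone, these counts were the same. In all 22161 genes were called, 11522 up and 10639 down (22405 without the libraries that stood apart), and 9028 up and 12776 down on log2(TPM + 0.1). The median of all genes was 0.09 with TMM, 0.205 with size factors and -0.09 with library totals.

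The line difference in the arsenite effect covered 11403 genes, 6355 higher and 5048 lower in Dmr-PERK cells (8994 and 3474 on log2(TPM + 1), 8168 and 3214 on log2(TPM + 0.1), and 11812 without the libraries that stood apart). CHRNA4 (no fold is given, since untreated Dmr-PERK cells had 0 counts), MYOCD (3.78 ± 0.26), DPYSL5 (3.60 ± 0.32), GRM8 (3.26 ± 0.25) and NTRK3 (3.17 ± 0.08) responded more in Dmr-PERK cells. ARL14EPL (-4.92 ± 0.19), DYRK1B (-2.74 ± 0.14) and GDF15 (-2.43 ± 0.11) responded less. So did PASD1 (-2.75 ± 0.38), which turned to 1.73 on log2(TPM + 1) and 0.86 on log2(TPM + 0.1). GCLM differed by 0.72 ± 0.03, ASNS by 0.52 ± 0.03 and SESN2 by -0.46 ± 0.05. DDIT3 (0.07 ± 0.06, edgeR adjusted p = 0.38), TRIB3 (-0.07 ± 0.05, adjusted p = 0.25) and HSPA1A (-0.11 ± 0.06, adjusted p = 0.167) did not pass. These means cover differences of both signs, which were not tested at single times. DDIT3 had log2 fold changes of 4.98 ± 0.08 in Dmr-PERK and 4.03 ± 0.07 in Parental cells at 4 h but 5.07 ± 0.08 and 5.57 ± 0.07 at 16 h. TRIB3 had 3.97 ± 0.07 and 4.30 ± 0.07 at 4 h but 5.20 ± 0.07 and 4.96 ± 0.07 at 24 h, and HSPA1A 5.83 ± 0.10 and 5.48 ± 0.10 at 8 h but 6.52 ± 0.11 and 7.26 ± 0.11 at 24 h. Over 8, 16 and 24 h, a mean chosen after seeing the data, the DDIT3 difference was -0.22 (edgeR adjusted p = 0.0102). The p53 targets (2 higher, 17 lower of 20, median -0.53, adjusted p = 9.55e-10 with an estimated correlation), hypoxia genes (2 and 11 of 15, adjusted p = 0.00225) and metallothioneins (0 and 5 of 8, adjusted p = 0.0249) responded less, and mitosis genes (19 and 0 of 20, adjusted p = 0.0202) had a higher response, 20 adjusted over the list alone. Ribosomal proteins were lower in 71 of 74 (72 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation) and mitochondrially encoded genes in 13 of 13 (adjusted p = 0.0938). ATF4/CHOP targets had 13 higher and 9 lower of 29 (adjusted p = 0.929).

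Dimerizer and thapsigargin were compared directly in Dmr-PERK cells over 5 times (n = 15 each). HSPA5 was at 893.5 ± 192.4 CPM with dimerizer and 8734 ± 3225 with thapsigargin (-3.22 ± 0.02), with SDF2L1 (-3.22 ± 0.04), DNAJB9 (-3.17 ± 0.02), MANF (-2.94 ± 0.03) and CDH15 (-3.86 ± 0.09) likewise lower with dimerizer. All 18 ER chaperones (median -1.76, adjusted p = 6.84e-07 with an estimated correlation), 23 of 24 XBP1-type genes (adjusted p = 2.14e-12) and 22 of 23 cholesterol synthesis genes (1 higher, median -0.89, adjusted p = 2.4e-06) were lower. Integrated stress response genes of the fixed panel lay closer, with ATF4 at -0.06 ± 0.02 (edgeR adjusted p = 0.000388), ASNS at 0.21 ± 0.02, CHAC1 at 0.25 ± 0.03 and TRIB3 at -0.26 ± 0.03. SESN2 was at -0.04 ± 0.03 (edgeR adjusted p = 0.245). The means of SESN2, ATF4 and CHAC1 cover differences of both signs, which were not tested at single times. SESN2 was at 117.3 ± 11.1 CPM with dimerizer and 168.8 ± 4.07 with thapsigargin at 2 h but at 207.5 ± 6.35 and 167.5 ± 7.04 at 24 h (SD, n = 3 each). ATF4 was at 512.2 ± 16.9 and 544.8 ± 6.29 at 2 h but 684.3 ± 13.9 and 607.7 ± 18.6 at 24 h. CHAC1 was at 58.5 ± 5.08 and 69.0 ± 0.419 at 2 h but 75.3 ± 1.42 and 56.8 ± 2.73 at 24 h. PPP1R15A (-0.73 ± 0.02) and DDIT3 (-1.75 ± 0.03) were lower with dimerizer. ATF4/CHOP targets had 9 higher and 15 lower of 29 (adjusted p = 0.483). Higher with dimerizer were DGAT2 (2.24 ± 0.04), BCAM (2.08 ± 0.03), TGM2 (2.03 ± 0.04), FOXS1 (1.89 ± 0.15) and KRT75 (1.81 ± 0.09), and matrix genes in 14 of 20 (4 lower, adjusted p = 0.0413). Adjusted over the list alone, these counts were the same. In all 12707 genes differed, 7060 higher and 5647 lower with dimerizer (13230 without the libraries that stood apart), but 4765 and 6069 on log2(TPM + 1) and 4849 and 5912 on log2(TPM + 0.1).

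Against arsenite, dimerizer gave far lower HSPA6 (-11.47 ± 0.09), HSPA7 (-10.42 ± 0.22), MT1H (3 counts against 3698), ATP13A4-AS1 (2 against 10443), HSPA1A (-8.17 ± 0.05) and HMOX1 (-7.95 ± 0.04). DDIT3 (-1.65 ± 0.03), PPP1R15A (-2.52 ± 0.02) and ATF4 (-0.43 ± 0.02) were lower too, but ASNS (0.47 ± 0.02) was higher. PTX3 (4.64 ± 0.09), NOG (3.87 ± 0.05), AMIGO2 (3.64 ± 0.06), TXNIP (3.64 ± 0.06) and SLFNL1 (3.52 ± 0.07) were higher with dimerizer. HSF1 genes were lower in 20 of 20 (median -2.495, adjusted p = 0.00886 with an estimated correlation) and metallothioneins in 8 of 8 (median -4.66, adjusted p = 0.00128). NRF2 genes were lower in 20 and higher in 5 of 26 (adjusted p = 0.0841 with an estimated correlation), mitosis genes higher in 19 and lower in 1 of 20 (adjusted p = 0.055) and ATF4/CHOP targets lower in 20 and higher in 8 of 29 (adjusted p = 0.328). Adjusted over the list alone, these counts were the same. In all 21697 genes differed, 10197 higher and 11500 lower with dimerizer (22011 without the libraries that stood apart), and the median of all genes was -0.12, or 0.03 with library totals.

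Of the genes called in Dmr-PERK cells, dimerizer and thapsigargin shared 5919 up and 6069 down. In opposite directions were 578 and 452 (up with the first named, then the second). Independent lists, in brackets below, would give 2290, 2407, 2384.5 and 2312. Across genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.773 and a covariance of 0.434, against 0.521 and 0.0399 in simulations of unchanged treatments that share the untreated wells. With the untreated wells parted, so that each treatment had its own 6, r was 0.621 and 0.634, the covariance 0.41 and 0.415, and 5311 and 5335 genes were shared up and 4958 and 5027 down. Dimerizer and arsenite shared 3295 up and 4346 down (3290 and 2934), with 3424 and 2223 opposite (2905.8 and 3321.5). At 2-fold 478 and 367 were shared (191.5 and 184) and 23 and 313 opposite (103.9 and 339.2). Covariance was 0.188 and r 0.171 (simulated 0.0396 and 0.511). With the wells parted r was 0.205 and 0.216 and the covariance 0.262 and 0.272. Thapsigargin and arsenite shared 4030 up and 5224 down (3699.6 and 3402), with 3329 and 2403 opposite (3267.5 and 3852.2). At 2-fold 825 and 727 were shared (403 and 325.9) and 69 and 431 opposite (218.6 and 600.7). Covariance was 0.373 and r 0.264 (simulated 0.0398 and 0.524). With the wells parted r was 0.287 and 0.292 and the covariance 0.46 and 0.466. All 3 treatments shared 2867 genes up and 3786 down (1016 and 943.4), of which 403 and 323 reached 2-fold in each (11.2 and 16).

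Untreated Dmr-PERK wells changed between 0 and 24 h (n = 3 each). CXCL8 (ENSG00000169429.10, chromosome 4, 73740506 to 73743716), a chemokine, fell from 129.1 ± 27.4 to 1.11 ± 0.163 CPM (-6.88 ± 0.24 by edgeR) and NR4A1, an immediate early receptor, from 599.3 ± 48.1 to 22.5 ± 3.76 CPM (-4.74 ± 0.08). NR4A3 (-5.66 ± 0.11), DUSP2 (-4.71 ± 0.10) and AP000892.6 (-4.67 ± 0.15) fell as well. HSPA1A rose from 89.1 ± 6.55 to 354.4 ± 18.6 CPM (1.99 ± 0.10), with HSPA1B (1.93 ± 0.10), APOBEC3D (1.85 ± 0.16), RAC3 (1.78 ± 0.16) and BMF (1.72 ± 0.12). All 18 immediate early genes fell (median -2.055, adjusted p = 1.6e-08 with an estimated correlation), 16 of 18 NF-kB genes fell (adjusted p = 2.64e-07), 16 of 20 matrix genes fell (adjusted p = 0.00599), 17 of 20 HSF1 genes rose (median 0.54, adjusted p = 0.00237) and all 20 mitosis genes rose (median 0.465, adjusted p = 0.00263). When adjusted over the list alone, 17 NF-kB genes fell and 20 HSF1 genes rose. ATF4/CHOP targets had 10 up and 6 down of 29, 7 down adjusted over the list alone (median 0.04, mean -0.03, test down, adjusted p = 0.962). In all 8394 genes were called, 3893 up and 4501 down (9119 without the libraries that stood apart), but 5435 up and 3391 down with library totals alone.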

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

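The tests of the untreated time course, of the ATF4/CHOP targets in Parental cells, of the line difference, of the HSF1 list at each of 4 times and the 4 of the Parental arsenite library were chosen only after the results were seen. The 3 patterns were picked from several looked at. A condition on the spread, added after the HSF1 median against 0 h had been seen, turned it from argued against to open. A like condition added for the ATF4/CHOP median, also after it had been seen, left that one as it was. The test of a weaker response, with its limit of 2 SE, replaced one on whole lists whose values had been seen.

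The effect of each treatment differed between the lines for many genes, by a direct test in edgeR. This held for 12678 genes with dimerizer, 6939 with thapsigargin and 11403 with arsenite. On average over 4 to 24 h EIF2AK3 fell with thapsigargin in Dmr-PERK cells and rose in Parental cells, a line difference of -2.76 ± 0.03. FKBP1A did the same (0.51 ± 0.02 in Parental cells), with a line difference of -1.03 ± 0.025. The opposite directions were seen from 8 h on. At 2 h EIF2AK3 was higher in both lines (0.11 ± 0.04 in Dmr-PERK and 1.76 ± 0.05 in Parental cells) and FKBP1A lower in both (-0.17 ± 0.035 and -0.185 ± 0.038). At 4 h EIF2AK3 did not pass in Dmr-PERK cells (-0.03 ± 0.04, edgeR adjusted p = 0.648), nor FKBP1A in Parental cells (-0.02 ± 0.04, adjusted p = 0.657). Counts of both genes in Dmr-PERK cells can hold reads of the construct.

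Dimerizer gave 2029 calls in Parental cells at 4 h (median absolute log2 fold change 0.28, 102 at least 2-fold), and edgeR gave 0 at 8, 16 and 24 h (1115, 1369 and 1399 at an unadjusted p under 0.05; DESeq2 called 2, 0 and 12). A response through the integrated stress response without the construct is argued against by the ATF4/CHOP targets, since it would raise them by about the change it explains (0.28) and their median was 0.037 with a standard error of 0.041, under a limit of 0.1. Of 29, edgeR called 3 higher, SESN2 (0.435 ± 0.092) among them, and 2 lower, and their r with Dmr-PERK dimerizer at 4 h was -0.09 (0.137 over 12332 genes of at least 5 CPM, which are not independent replicates). Library size (2.06e+07 to 4.01e+07 counts untreated, 1.96e+07 to 2.18e+07 with dimerizer) is argued against too, since of 2415 calls in a fit of these 6 libraries 2029 were called again among the 2155 after thinning each to 1.96e+07. A different position along the course of the untreated wells may contribute and stays open, since across genes, which are not independent replicates, the 4 h difference had r = 0.13 with the change of untreated Parental cells from 0 to 8 h. That r was 0.555 over 12332 genes of at least 5 CPM, a limit chosen after the first value was seen and so not decisive, and 88.1% of the called genes had the sign of that change, such as NR4A1 (-0.91 ± 0.06 against -5.84 ± 0.08).

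HSF1 heat shock genes were lower with dimerizer than in time-matched untreated Dmr-PERK wells (median -0.62). Scaling of the libraries is argued against by a median of -0.627 on library totals and -0.63 with DESeq2 size factors. The mean of 4 to 24 h does not decide on a rise of these genes in untreated wells as the whole cause. Against untreated 0 h its median was -0.128 ± 0.14 (SE), 5 members higher and 11 lower, while the untreated median was 0.50. At 8 h, within that mean, the rise is argued against as the whole cause. The median there was -0.347 ± 0.143, 2 members higher and 13 lower. At 4 h the median with dimerizer does not decide (-0.206 ± 0.168, 1 higher and 12 lower). Untreated wells, however, had not risen at 4 h against 0 h (median 0.018 ± 0.07, 1 higher and 2 lower). That argues against this cause at 4 h too, a reading made after the values were seen. It stays open at 16 h (0.096 ± 0.186, 7 and 6), and at 24 h the median it needs is there (0.269 ± 0.197, 10 and 4). HSPA1A (-0.975 ± 0.081) and HSPA8 (-0.54 ± 0.04) lay below their 0 h level on average, from -2.04 ± 0.12 and -1.22 ± 0.05 at 4 h to 0.26 ± 0.10 (edgeR adjusted p = 0.0238) and 0.09 ± 0.05 (adjusted p = 0.113) at 24 h. HSPH1 did not pass (0.03 ± 0.05, adjusted p = 0.666). Activation of the dimerizable kinase by the ligand is a hypothesis, found and tested on the same data, with the value it needs, a line difference with a median of -0.667 and 18 members lower.

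Replicate 3 of Parental arsenite at 24 h stood apart, with CCL2 at 5.16 CPM against 0.183 in the others and MT-ND4L at 407 against 1940. A wrong label is argued against by a correlation of log2 CPM across 12332 genes of at least 5 CPM of 0.96 with the mean of its 2 other replicates and at most 0.932 with the mean of another group (Parental arsenite at 16 h). RNA of untreated cells mixed in may contribute and stays open: the estimated share was 12.3%, and the lowest decile of 256 genes fallen at least 8-fold stood at 10.67% of untreated, near that share, against 5.06% in the others. On the other side, that share would lower raised metallothioneins by -0.187, where they were higher by 0.272 ± 0.164, the 1 of 4 stress lists over 2 standard errors (SE) above it. A response weaker by 1 factor for all genes is argued against: at the slope of 0.834 on the others it would move list members raised at least 2-fold by -0.468 (ATF4/CHOP), -0.441 (HSF1), -0.403 (NRF2) and -0.842 (metallothioneins). Their medians were -0.107 ± 0.087, -0.096 ± 0.086, 0.071 ± 0.154 and 0.272 ± 0.164 (SE), in 4 of 4 lists over 2 SE above. A slower response is argued against by r = 0.059 across 12332 genes, not independent replicates, between its deviation and the difference of 16 from 24 h of arsenite. The medians of the whole lists were -0.025 ± 0.08, -0.08 ± 0.11, 0.109 ± 0.094 and 0.272 ± 0.164, and a weaker response of some genes only was not tested.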

How the results depend on the processing

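The mean over 8, 16 and 24 h and the fit without a pair of libraries that stood apart were chosen only after the results were seen. Counts of calls over several times stayed within 1.5 times under the settings run, except as follows. With dimerizer, thapsigargin and arsenite in turn, a minimum of 2-fold as well left 2070, 3915 and 10677 genes in Dmr-PERK cells, 7, 4071 and 9835 in Parental cells and 1978, 476 and 1470 line differences. It left 777 and 8384 for dimerizer against thapsigargin and arsenite, 2943 between the lines, 1235 over time untreated and 726 of the 6653 genes that 3 treatments shared. The Parental dimerizer count of 157 became 282 with DESeq2, 94 without a filter, 341 in a fit of its own libraries and 28 and 14 on log2(TPM + 1) and log2(TPM + 0.1). It was 2861 with all untreated times averaged, 384 minus the libraries that stood apart and, in edgeR, 0 over 8, 16 and 24 h (1356 at an unadjusted p under 0.05), a mean not run in DESeq2. The stricter filter left 14592 genes with arsenite in each line and 14387 for dimerizer against arsenite, since fewer genes were tested. Of 198 list calls, 73 held with an estimated correlation. Of 30 counts at single times, 30 stayed within 1.5 times with size factors and with library totals, 27 with DESeq2, 25 with the stricter filter, 22 with all untreated times averaged and 5 at 2-fold, as did 2 of 6 at 2 h set against untreated 4 h. Except where the construction shows it, the cause was not tested.

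Leaving out 1 replicate of every group gave 13164 to 13885 genes with dimerizer, 15480 to 16043 with thapsigargin and 21282 to 21796 with arsenite in Dmr-PERK cells. In Parental cells it gave 16127 to 16724 with thapsigargin and 20819 to 21155 with arsenite. Parental dimerizer gave 4 (without replicate 2) to 126. Line differences were 10859 to 11778, 4581 (without replicate 2) to 6063 and 9124 to 10234. Dimerizer against thapsigargin gave 10933 to 11539 and against arsenite 20309 to 20643. Time dependence, not run in DESeq2, had 8272 to 10652, 11661 to 13031 and 16724 to 17404. Untreated lines gave 15143 to 15877 and untreated cells over time 6087 to 7439. Without 1 library the counts were 14641 to 14834, 16820 to 17022 and 22471 to 22885 in Dmr-PERK cells and 116 to 184 for Parental dimerizer, and other comparisons were not run so. Each left-out fit assumes that all groups vary alike.

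Some genes changed sign. CHAC1 in dimerizer against arsenite was -0.035 with DESeq2, -0.034 with its size factors and -0.119 with the stricter filter. FKBP1A with arsenite in Dmr-PERK cells was -0.083 with library totals and -0.07 on both TPM scales, and HERPUD1 in dimerizer against arsenite 0.084, 0.109 and 0.11. PASD1 in the arsenite line difference was 1.726 and 0.86 on TPM. DNAJB9 with arsenite in Parental cells was 0.061 with the stricter filter and 0.307 over 8, 16 and 24 h. With all untreated times averaged, Parental dimerizer gave 0.053 for ATF4, -0.232 for PPP1R15A and -0.155 for DNAJB9. Over 8, 16 and 24 h it gave 0.08 for DUSP2 and 0.103 for RGS4, and line differences were -0.198 (thapsigargin) and -0.22 (arsenite) for DDIT3 and -0.15 (arsenite) for HMOX1. The fry test turned the direction of the eIF2 pathway (adjusted p = 9.34e-34) and housekeeping genes (4.5e-14) with arsenite in Dmr-PERK cells, and of both in Parental cells (2.01e-28 and 0.0126). It also turned that of NRF2 genes with thapsigargin in Parental cells (9.06e-07). It tests direction within a list, and not against other genes. It left 259 of 364 list results the same, lost 4 calls and, besides the 5 turned, added 96 calls in the direction camera gave. Of 516 named values, 512 kept direction and call with size factors and with library totals, 511 without a filter, and 491 and 492 on log2(TPM + 0.1) and log2(TPM + 1), where 17 and 16 lost the call. With DESeq2 510 of 513 did, and without 1 replicate of every group 1511 of 1548, where 33 lost the call.

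With the replicate number as a block, the counts were 14914, 17035 and 22556 in Dmr-PERK cells and 157, 17568 and 22169 in Parental cells. The block moved no other count by over 1.5 times, and 516 of 516 named values kept their call. The numbers do not pair the samples. In 0 of 30 comparisons were all 3 correlations of same-numbered deviations over 0.1 (12332 genes), and their mean was 0.003 against -0.001 for other numbers. In 3 of 30 every sample correlated best with its own number. Depth limits genes of few counts. No fold is given for a group with 1 to 3 counts. Those from few counts are less sure than their ±, such as 8.34 ± 0.39 for SPRR2D with thapsigargin in Parental cells (9 untreated counts).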

Other observations

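Which lists and times to describe was chosen only after the results were seen, as was the form of the splits for time dependence, while the tests of other splits were not.

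Ribosomal protein genes moved both ways over the dimerizer course in Dmr-PERK cells, with 2 h set against untreated 0 h. By edgeR 45 of 74 were lower and 0 higher at 2 h (median -0.17), and 69 were lower at 4 h (-0.24). At 16 h 55 were higher and 2 lower (0.25), and at 24 h 68 were higher and 2 lower (0.37). Adjusted over the list alone, 60 were lower at 2 h, 70 at 4 h, and 57 and 69 were higher at 16 and 24 h. Ribosome biogenesis genes had 21 of 23 lower at 2 h (-0.27) and all 23 higher at 24 h (0.96). Immediate early genes were higher in all 18 at 2 h (0.895), and at 24 h 8 were higher and 5 lower (0.21). Mitosis genes had 5 of 20 higher at 2 h, 7 adjusted over the list alone (0.09), and all 20 lower at 24 h (-0.91). Cholesterol genes had 22 of 23 lower at 24 h with dimerizer (-0.995). With thapsigargin 20 of 23 were higher at 2 h and 1 lower, 21 and 2 adjusted over the list alone (0.75). The medians given kept their sign under each scaling.

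With arsenite, many NF-kB and inflammatory genes were lower early but fewer at 24 h. In Dmr-PERK cells 15 of 18 were lower at 2 h (median -0.68) and 14 at 4 h (-1.12), and 11 were higher and 7 lower at 24 h (1.65). In Parental cells 14 were lower at 2 h (-0.73), and 11 were higher and 5 lower at 24 h (1.45). Of 10 blood cell markers, of another cell type, 6 passed the filter, as a gene can by its rise alone. In Dmr-PERK cells 5 were higher at 16 and 24 h (3.08 and 3.01), as were 11677 of all 26998 genes at 24 h. In Parental cells 5 were higher and 1 lower at 24 h (4.38). HBA2, a globin gene, had 1 count in untreated Dmr-PERK libraries and 1255 with arsenite, and CD14 rose by 2.35 ± 0.31. By adjustment over the list alone, 15 NF-kB genes were lower in Parental cells and 1 higher in Dmr-PERK cells at 2 h. Other counts were the same. The medians given kept their sign under each scaling, and list tests were not run at single times.

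Other splits of each comparison's own libraries were fitted with edgeR, 40 with the real one included. Where 1 split, the real one, reached its value, a random assignment of these wells is an unlikely source of the count. Any steady difference between sets of wells would give the same outcome, also one of culture or plate, so such differences are not excluded. In the comparisons that follow only the real split reached its value. In Dmr-PERK cells this held for dimerizer (15243 genes, highest other split 10247), thapsigargin (17152, 2544) and arsenite (22504, 7810). It held in Parental cells for thapsigargin (17800, 13762) and arsenite (21727, 8139). Line differences had 13158 with dimerizer (259), 7688 with thapsigargin (370) and 10475 with arsenite (59). Dimerizer differed from thapsigargin in 13001 genes (6282) and from arsenite in 21639 (17080), and the untreated lines in 17204 (5669). For time dependence the wells of each treatment were parted over 4 times anew. That gave 12068 with dimerizer (3863), 14366 with thapsigargin (5243) and 18959 with arsenite (10). Such splits also mix the change with time of untreated wells, so they cannot decide. Chance cannot be excluded for Parental dimerizer (341, highest other 363, with 3 splits as large).

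Untreated 24 h against 0 h (8869, highest other 0) and each single time had 10 splits, too few for a share under 0.05. Single times in Dmr-PERK cells gave 4466 to 13262 genes with dimerizer, 9571 to 14786 with thapsigargin and 5737 to 22000 with arsenite. In Parental cells they gave 8352 to 15371 with thapsigargin and 5431 to 21361 with arsenite, and no other split of these passed 2. Parental dimerizer gave 58 at 2 h (highest other 24), 2415 at 4 h (1), 1 at 8 h (13, with 9 as large), 0 at 16 h (51, with 10 as large) and 20 at 24 h (14).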
